A study of Melampsora laricis-populina with 9 samples.

How the data were processed

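Libraries of 3 sexual stages of Melampsora larici-populina were grouped by the stage named in the labels: basidia (3 libraries), pycnia (2 analysed here of 3 in the series) and aecia (3). Per the labels' protocols, total RNA of basidia samples was isolated with a plant RNA column kit in several rounds from small amounts of material, and that of pycnia and aecia samples from infected larch needles with a method adapted to conifers. Libraries were built with a TruSeq RNA kit and sequenced as read pairs, per the labels.

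Each deposited file holds, per the file headers, the count of uniquely mapped reads for each of 16399 gene models of the version 1 genome of the Joint Genome Institute, from a tool the header calls CLC. Its version, the mapping settings, trimming and strand setting are not given in the sources used here. Because only unique reads were counted, genes with a near-identical copy elsewhere in the genome lose reads, and their levels are uncertain. The deposited normalized signal, per the file headers, is the authors' DESeq2 normalized count. The submitters' processing notes name DESeq2 1.10.1 and edgeR 3.12.0. In each file this signal equalled the count divided by 1 constant per library, and that constant was 1.05 to 1.06 times the size factor recomputed from the 8 libraries. The signal was used only for this check. All tests used the deposited counts.

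Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the stages (minimum 10 reads, minimum total 15), which left 10340. Libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per stage was fitted to all 8 libraries, so that all stages share an estimate of the spread. Each of the 3 comparisons was tested two-sided with glmQLFTest, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. A fold against a stage without reads is a lower bound computed against a floor of 3 reads in each library of that stage, and counting intervals are at the 95% level. Bounds and intervals cover counting error only, since reads are not independent molecules. CPM values use TMM-scaled library totals.

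Before the data were examined, 41 gene lists, the rule for named genes, the tests and most alternatives were fixed. Of the lists, 40 are defined by product words or protein motifs and were not used here, for want of an annotation. The remaining list holds 19 published candidate effectors identified by protein number. Of these, 16 are in the files, Mlp124478, Mlp124466 and Mlp124497 were not analysed here, and 7 were tested. The list was tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 and a prior count of 2, adjusted over the 3 comparisons, and again with an estimated correlation. Named genes are the 2 with the largest absolute log2 fold change in each direction of each comparison, among called genes whose libraries do not overlap between stages and whose mean is at least 50 CPM in the higher stage. The rule also takes the most abundant gene of each stage and the tested list members. Figures were drawn with matplotlib 3.10.9.

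Depth was 63902311 to 65756953 reads in basidia, 13674207 to 14244025 in pycnia and 16610790 to 21906385 in aecia, so a gene at 1 CPM rests on more reads in basidia. Replicates were compared by a chi-square test of their counts. The statistic per gene was 8.53 to 13.2 for basidia and pycnia pairs and 54.6 to 228 for aecia pairs, so no pair agreed within sampling noise. The scripts were tested on simulated data with 200 changed genes per comparison. Each gene had its mean over all libraries, the real library sizes were kept, and a single trend of spread served all stages. The simulation held neither the larger spread of aecia nor the many changed genes of the real data. Its rates therefore check the scripts and do not describe the real comparisons. Of 100 genes changed by a log2 fold of 2, the test found 73% for pycnia against basidia (10177 genes tested), 69% for aecia against basidia (10198) and 73% for aecia against pycnia (10179). At a log2 fold of 1 it found 31%, 34% and 26%. False calls made up 10.3%, 3.74% and 3.88% of all calls.

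The alternatives fixed in advance were median-of-ratios size factors, upper-quartile factors, no filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a fit of only the 2 stages compared, the replicate number as a block, counts thinned to the smallest library, an adjusted p under 0.01, a minimum absolute log2 fold change of 1, and each library left out in turn. Alternatives chosen after seeing the data were aecia replicates 1 and 2 both left out, only genes of at least 20 CPM, library totals alone, limma-voom with library quality weights, and robust quasi-likelihood estimation.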

Results

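RNA sequencing profiled 3 sexual stages of the poplar leaf rust fungus Melampsora larici-populina, isolate 98AG31. This rust needs both a poplar and a larch host to complete its life cycle. Basidia grow out of overwintered telia on fallen poplar leaves and release basidiospores, which infect larch needles, where pycnia (the organs of mating) and then aecia (the organs that release the spores that infect poplar) develop. The basidia libraries (n = 3) were made from dead leaves of Populus trichocarpa left outdoors over winter, so they held leaf, telia, basidia and basidiospores together. Pycnia and aecia libraries were made from whole infected larch needles collected 1 and 2 weeks after inoculation. Aecia had n = 3 libraries. Pycnia had n = 2, because the file of pycnia replicate 2 was not analysed here. The labels call the libraries of a stage biological replicates without saying whether they came from separate inoculations, so p-values measure only the spread between these samples.

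Uniquely assigned fungal reads totalled 63902311 to 65756953 per library in basidia, 13674207 to 14244025 in pycnia and 16610790 to 21906385 in aecia. Of 16399 gene models, 4552 (27.8%) had no read in any of the 8 libraries, 10340 had enough reads to be tested, and 5060 reached at least 10 CPM (the count scaled to a common library total) in every library. A floor of 3 reads corresponded to 0.0613 CPM in the deepest library and 0.173 CPM in the shallowest, counting error only. Gene levels are given as mean CPM ± SD after scaling by trimmed mean of M-values (TMM). Genes are named by their protein number in the genome's gene set behind the prefix Mlp, the form used for published effector candidates of this fungus. The files do not pair these numbers with products, and gene positions were not used here.

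The gene with the most reads differed between the stages. Mlp47226 led in basidia at 25662 ± 891 CPM (SD, n = 3), against 123 CPM in pycnia and 194 CPM in aecia. Mlp101353 led in pycnia at 33096 ± 276 CPM (SD, n = 2), against 6.18 CPM in basidia and 4811 CPM in aecia, and held 4.18% of the reads of pycnia replicate 1. Mlp34673 led in aecia at 21709 ± 6528 CPM (SD, n = 3), against 8.84 CPM in basidia and 6229 CPM in pycnia. Among the 100 most abundant genes of each stage, aecia and pycnia shared 72, pycnia and basidia 14, and aecia and basidia 15. Across genes, log2 CPM values of basidia libraries correlated with those of larch libraries at 0.542 to 0.567, and pycnia with aecia at 0.913 to 0.958. Replicates correlated at 0.998 to 0.999 in basidia, 0.993 in pycnia and 0.907 to 0.967 in aecia, where genes are not independent observations. In a principal component analysis, the first component held 87.5% of the variance and parted basidia from all larch libraries. The second held 6.44% and set aecia replicate 1, at 80.1, apart from the other 7 libraries, at -31.0 to 0.42.

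The comparison of pycnia with basidia asks which genes differ between infected larch needles and the spore-forming tissue on dead poplar leaves. Among the 7 published candidate effectors with enough reads, 5 were higher in pycnia, 1 was lower and 1 did not pass the test. Effectors are secreted proteins thought to act on the host plant. The chloroplast-targeted candidate CTP1 (Mlp107772) had 8.39 ± 0.86 CPM in pycnia (SD, n = 2) against 0.83 ± 0.24 in basidia (SD, n = 3), a log2 fold change of 3.33 ± 0.33 (SE). Mlp72983 stood at 4972 ± 155 CPM in pycnia (SD, n = 2) against 4.96 ± 4.72 in basidia (SD, n = 3), a log2 fold change of 9.97 ± 0.84 (SE). Its basidia level rested mostly on replicate 2, at 10.4 CPM against 1.84 and 2.65 CPM, and without that library the log2 fold change was 11.09. Basidia replicate 2 also had higher levels at the low end of the larch-abundant genes. Over 77 genes of at least 1000 CPM in the larch stages, the 5th percentile was 0.124% of the larch level there. It was 0.035% and 0.064% in basidia replicates 1 and 3. The source of such reads was not tested. Mlp124499 had 76.4 ± 11.7 CPM in pycnia (SD, n = 2) and 7 reads over the 3 basidia libraries, a ratio of 1555 with a 95% counting interval of 751 to 3849. Mlp124017, a candidate with a solved protein structure, had 10.4 ± 0.55 CPM in pycnia (SD, n = 2) and no read in basidia, so it was at least 164-fold higher against a floor of 3 reads per library. Mlp124256 had 8.14 ± 0.34 CPM in pycnia (SD, n = 2) and 1.5 ± 0.32 in basidia (SD, n = 3). Mlp124111 went the other way, with 795 ± 40.5 CPM in basidia (SD, n = 3) and 4.85 ± 0.09 in pycnia (SD, n = 2), a log2 fold change of -7.36 ± 0.55 (SE). Mlp123218 had 3.54 ± 0.32 CPM in basidia (SD, n = 3) and 0.80 ± 0.42 in pycnia (SD, n = 2) and did not pass (adjusted p = 0.324, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

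By the same test, adjusted p was 7.6e-05 for Mlp107772, 3.1e-05 for Mlp72983, 9.6e-07 for Mlp124499, 0.0160 for Mlp124017, 0.0121 for Mlp124256 and 1.7e-05 for Mlp124111 (edgeR with Benjamini-Hochberg adjustment). Adjusted over the list alone, 5 were again higher and 1 lower. As a set, the 7 genes were not shown to stand apart from the other genes, with a median log2 fold change of 3.33 and camera adjusted p = 0.201 (adjusted p = 0.370 with an estimated correlation). Without pycnia replicate 1 or replicate 3, the edgeR adjusted p of Mlp124017 was 0.0512 or 0.0510, and that of Mlp124256 was 0.0582 or 0.0502; Mlp124256 was also lost without basidia replicate 2 or replicate 3, at 0.0502 or 0.0539. Mlp123218 passed with only the 2 stages fitted (edgeR adjusted p = 1.1e-04), without aecia replicate 3 (0.0290), with aecia replicates 1 and 2 both left out (1.5e-04) and with limma-voom with quality weights (0.0012).

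Over all genes, 3260 were higher and 3022 lower in pycnia than in basidia, 60.8% of those tested. These counts rest on a spread shared with aecia, whose replicates differed most. With only pycnia and basidia fitted, 4603 were higher and 4444 lower of 10475 tested. The pycnia and basidia libraries did not overlap for 9427 of the 10340 genes tested, where chance gives 20%. Changes of over 4-fold were seen for 1839 higher and 1389 lower genes, and changes of over 16-fold for 1174 and 685. Among genes of at least 20 CPM in the higher stage the balance turned, with 1008 higher and 1221 lower by over 4-fold. The 1174 genes higher by over 16-fold held 24.6% ± 0.67 of pycnia reads (SD, n = 2) and 0.145% ± 0.008 of basidia reads (SD, n = 3). The 685 lower ones held 39.8% ± 0.46 of basidia reads (SD, n = 3) and 0.739% ± 0.020 of pycnia reads (SD, n = 2). Mlp110449 had 153 ± 0.37 CPM in pycnia (SD, n = 2) and no basidia read, at least 2406-fold higher (adjusted p = 1.2e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Mlp66943 had 137 ± 6.62 CPM in pycnia (SD, n = 2) and no basidia read, at least 2156-fold higher. Mlp30131 had 126 ± 5.89 CPM in basidia (SD, n = 3) and no pycnia read, at least 743-fold lower in pycnia. Mlp85557 had 75.7 ± 2.46 CPM in basidia (SD, n = 3) and no pycnia read, at least 445-fold lower in pycnia. The share of calls that were higher, 51.9%, depended on the scaling: it was 63.9% with upper-quartile factors and 72.9% with library totals alone, which moved the median log2 fold change of all genes by 0.42 and 0.79. Host, growth outdoors and the RNA isolation kit also differed between basidia and the larch stages, so they and the stage cannot be told apart in either comparison with basidia.

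**Figure D1:**
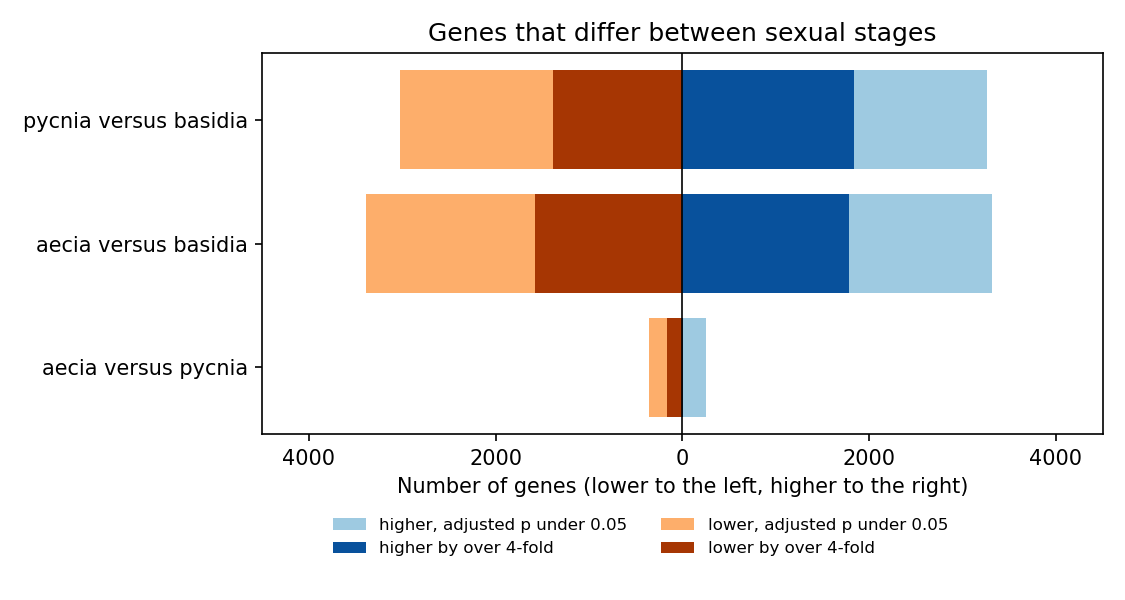
Number of genes higher (to the right, blue) or lower (to the left, orange) in the first-named stage of each comparison by edgeR's quasi-likelihood test, with the dark part of each bar for changes of over 4-fold. Both comparisons with basidia have long bars, with 3260 higher and 3022 lower in pycnia and 3320 higher and 3385 lower in aecia, against 256 higher and 358 lower between aecia and pycnia.

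The comparison of aecia with basidia asks the same of the later larch stage. The candidate effectors again gave 5 higher, 1 lower and 1 that did not pass. Mlp72983 had 5205 ± 589 CPM in aecia (SD, n = 3), a log2 fold change of 10.04 ± 0.83 (SE) over basidia, and 11.18 without basidia replicate 2. Mlp124499 had 182 ± 13.9 CPM in aecia (SD, n = 3), a ratio of 3706 to its 7 basidia reads with a 95% counting interval of 1790 to 9174. CTP1 (Mlp107772) had 29.3 ± 2.94 CPM in aecia (SD, n = 3), a log2 fold change of 5.14 ± 0.34 (SE). Mlp124017 had 5.78 ± 5.60 CPM in aecia (SD, n = 3), a mean at least 91.1-fold above the floor in basidia. Aecia replicate 1 had no read for it, like the basidia libraries, so the bound does not hold for that library. The fitted log2 fold change of Mlp124017 was 10.47, and 9.62 to 11.09 with single libraries left out. It was 9.37 with counts thinned to the smallest library and 6.44 with limma-voom. Mlp124256 had 4.47 ± 3.07 CPM in aecia (SD, n = 3), a log2 fold change of 1.57 ± 0.58 (SE) that dropped to 0.85 without aecia replicate 2, which held 8.01 CPM against 2.88 and 2.53 CPM. Mlp124111 had 1.5 ± 1.02 CPM in aecia (SD, n = 3), a log2 fold change of -9.09 ± 0.50 (SE), and -9.72 without aecia replicate 3. Mlp123218 had 0.28 ± 0.48 CPM in aecia (SD, n = 3) and did not pass (adjusted p = 0.0803, edgeR with Benjamini-Hochberg adjustment).

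In this comparison, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 2.3e-05 for Mlp72983, 4.1e-07 for Mlp124499, 7.0e-06 for Mlp107772, 0.0173 for Mlp124017, 0.0455 for Mlp124256 and 2.8e-06 for Mlp124111. Adjusted over the list alone, 5 were higher and 1 lower. The set as a whole did not pass (median log2 fold change 5.14, camera adjusted p = 0.201; adjusted p = 0.370 with an estimated correlation). Mlp124256 was lost without basidia replicate 1, 2 or 3, pycnia replicate 1 or 3, or aecia replicate 2 (edgeR adjusted p = 0.0819 to 0.143). It was also lost with no filter on low counts, with only the 2 stages fitted and with thinned counts (edgeR adjusted p = 0.0540, 0.0691 and 0.0693), with limma-voom without or with quality weights (0.0518 and 0.0734), and with aecia replicates 1 and 2 both left out (0.0745). The call of Mlp124017 was lost with limma-voom (log2 fold change 6.44, adjusted p = 0.126). Mlp123218 passed without aecia replicate 1 or replicate 3 or both replicates 1 and 2 (edgeR adjusted p = 0.0415, 8.0e-04 and 0.0015). Its log2 fold change went from -3.70 to -9.84 without aecia replicate 3, the only aecia library with reads for it. It also passed with DESeq2 (0.0317) and with limma-voom without or with quality weights (0.0030 and 0.0216).

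**Figure D2:**
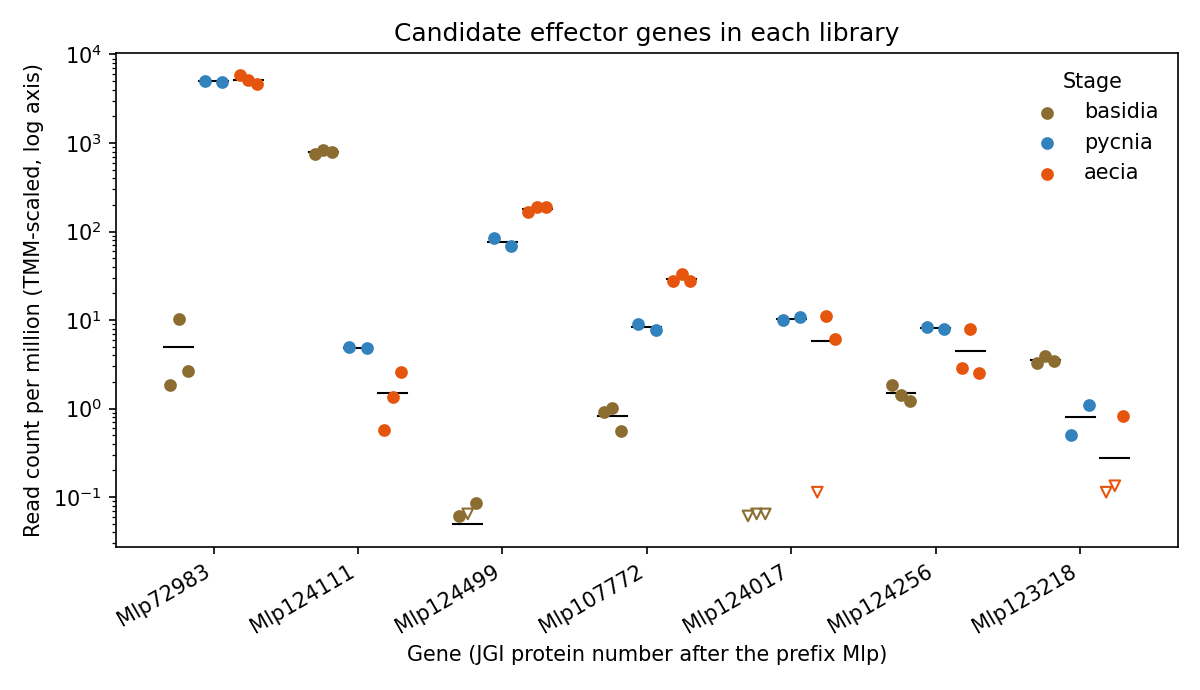
Read counts as CPM (log axis) of the 7 tested candidate effectors in each basidia, pycnia and aecia library, with black lines for stage means and open triangles at the 3-read floor for libraries without reads. Mlp72983 averages 4972 CPM in pycnia and 5205 CPM in aecia against 4.96 CPM in basidia, and Mlp124111 averages 795 CPM in basidia against 4.85 and 1.5 CPM in pycnia and aecia.

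Of all genes, 3320 were higher and 3385 lower in aecia than in basidia, 64.8% of those tested. The libraries of these stages did not overlap for 7478 of the 10340 genes tested, where chance gives 10%. Over 4-fold changes were seen for 1780 higher and 1577 lower genes, and over 16-fold changes for 1070 and 833. Here too the balance turned among genes of at least 20 CPM in the higher stage, with 974 higher and 1256 lower by over 4-fold. The 1070 genes higher by over 16-fold held 25.8% ± 0.87 of aecia reads (SD, n = 3) and 0.168% ± 0.009 of basidia reads (SD, n = 3). The 833 lower ones held 40.8% ± 0.46 of basidia reads (SD, n = 3) and 0.669% ± 0.19 of aecia reads (SD, n = 3). Mlp114535 had 67.2 ± 3.51 CPM in aecia (SD, n = 3) and no basidia read, at least 1058-fold higher (adjusted p = 7.6e-07, edgeR with Benjamini-Hochberg adjustment). Mlp62969 had 61.2 ± 14.9 CPM in aecia (SD, n = 3) and no basidia read, at least 964-fold higher. Mlp73151 had 275 ± 15.6 CPM in basidia (SD, n = 3) and no aecia read, at least 2043-fold lower in aecia. Mlp113516 had 105 ± 2.73 CPM in basidia (SD, n = 3) and no aecia read, at least 784-fold lower in aecia. Of the calls, 49.5% were higher, against 61.2% with upper-quartile factors and 67.5% with library totals alone, which moved the median log2 fold change by 0.43 and 0.67.

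The comparison of aecia with pycnia follows the fungus within larch needles between 1 and 2 weeks after inoculation. Among the candidate effectors, 2 rose and none of the other 5 passed the test. Mlp107772 rose from 8.39 ± 0.86 CPM (SD, n = 2) to 29.3 ± 2.94 CPM (SD, n = 3), a log2 fold change of 1.81 ± 0.34 (SE; adjusted p = 0.0239, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Mlp124499 rose from 76.4 ± 11.7 CPM (SD, n = 2) to 182 ± 13.9 CPM (SD, n = 3), a log2 fold change of 1.25 ± 0.28 (SE; edgeR adjusted p = 0.0423). Mlp72983 was at 4972 CPM in pycnia and 5205 CPM in aecia, a difference smaller than the SD of aecia (589) but not that of pycnia (155), and did not pass (log2 fold change 0.07 ± 0.63 SE, edgeR adjusted p = 0.975). Mlp124111 had 4.85 CPM in pycnia and 1.5 CPM in aecia and did not pass over all genes (edgeR adjusted p = 0.0710). Adjusted over the list alone it passed (adjusted p = 0.0139), which gave 2 higher and 1 lower. Mlp124017, Mlp124256 and Mlp123218 had log2 fold changes of -0.85, -0.86 and -1.55 with edgeR adjusted p of 0.861, 0.512 and 0.686. With single libraries left out, these folds ranged from -1.74 to -0.26 for Mlp124017, from -1.57 to -0.58 for Mlp124256 and from -7.70 (without aecia replicate 3) to -0.89 for Mlp123218. As a set, the 7 genes had a median log2 fold change of -0.85 and a mean of -0.27, while camera's direction was upward (adjusted p = 0.798; adjusted p = 0.832 with an estimated correlation).

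Over all genes, 256 were higher and 358 lower in aecia than in pycnia, 5.94% of those tested. The libraries of the 2 stages did not overlap for 3669 of the 10340 genes tested, where chance gives 20%. Falls of over 4-fold outnumbered rises of that size, with 162 genes against 9. Of the 162, 103 had at least 20 CPM in pycnia. Mlp37534 rose from 66.0 ± 14.6 CPM (SD, n = 2) to 437 ± 225 CPM (SD, n = 3), a log2 fold change of 2.73 ± 0.50 (SE; adjusted p = 0.0221, edgeR with Benjamini-Hochberg adjustment). Mlp111613 rose from 10.4 ± 1.25 CPM (SD, n = 2) to 58.0 ± 28.1 CPM (SD, n = 3), a log2 fold change of 2.48 ± 0.39 (SE; edgeR adjusted p = 0.0142). Mlp85159 went from 55.3 ± 3.52 CPM (SD, n = 2) to 3.43 ± 1.78 CPM (SD, n = 3), a log2 fold change of -4.01 ± 0.68 (SE; edgeR adjusted p = 0.0168). Mlp60374 went from 54.4 ± 5.41 CPM (SD, n = 2) to 4.36 ± 2.54 CPM (SD, n = 3), a log2 fold change of -3.64 ± 0.69 (SE; edgeR adjusted p = 0.0253). Mlp101353, the leading gene of pycnia, had a log2 fold change of -2.78 ± 0.47 (SE; edgeR adjusted p = 0.0167). Mlp34673, the leading gene of aecia, had 1.80 ± 0.57 (SE) and did not pass (edgeR adjusted p = 0.121).

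These calls depended on which libraries were used. Aecia replicates 1 and 2 had no read for 30.1% and 14.1% of the genes at 2 to 5 CPM in pycnia, against 1.17% in aecia replicate 3 and 0 in both pycnia libraries. With aecia replicates 1 and 2 both left out, 1774 genes were higher and 2053 lower, including 256 and 351 of the genes above, with a single aecia library assumed to vary like the other stages. Without aecia replicate 1, the counts were 858 and 1153; without aecia replicate 2, 464 and 497; and without aecia replicate 3, 473 and 968. Without pycnia replicate 1 they were 11 and 56, and without pycnia replicate 3 they were 8 and 56, each with a single pycnia library assumed to vary like the other stages. Leaving out basidia replicate 1, 2 or 3, which enter through the shared estimate of spread, gave 127 and 201, 141 and 205, or 124 and 193. Mlp37534, Mlp111613, Mlp85159, Mlp60374, Mlp107772, Mlp124499 and Mlp101353 all lost their calls when either pycnia library was left out (edgeR adjusted p = 0.119 to 0.381). Mlp37534 and Mlp107772 were also lost without basidia replicate 1 (0.0523 and 0.0571), and Mlp60374 without basidia replicate 2 or 3 (0.0509 and 0.0510). Mlp124499 was lost without basidia replicate 1 or 3 (0.104 and 0.0788) and without aecia replicate 2 or 3 (0.0501 and 0.0550; all edgeR adjusted p). With only the 2 stages fitted, Mlp37534, Mlp111613 and Mlp107772 did not pass (edgeR adjusted p = 0.0621, 0.0513 and 0.0523), and with limma-voom Mlp111613 did not (0.0538). Calls were gained for Mlp34673 without aecia replicate 1 or basidia replicate 2 (0.0451 and 0.0444), Mlp124111 without aecia replicate 1 or 3 (0.0121 and 0.0131) and Mlp123218 without aecia replicate 3 (0.0162; all edgeR adjusted p). Mlp34673 also passed with only the 2 stages fitted (edgeR adjusted p = 0.0397), with DESeq2 (0.0049) and with limma-voom without or with quality weights (0.0049 and 9.7e-05), and Mlp124111 with DESeq2 (0.0033). With aecia replicates 1 and 2 both left out, Mlp34673, Mlp124111 and Mlp124256 passed (edgeR adjusted p = 0.0024, 0.0064 and 0.0055). The share of calls that were higher was 41.7%, against 27.4% with library totals alone, which moved the median log2 fold change by -0.11.

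**Figure D3:**
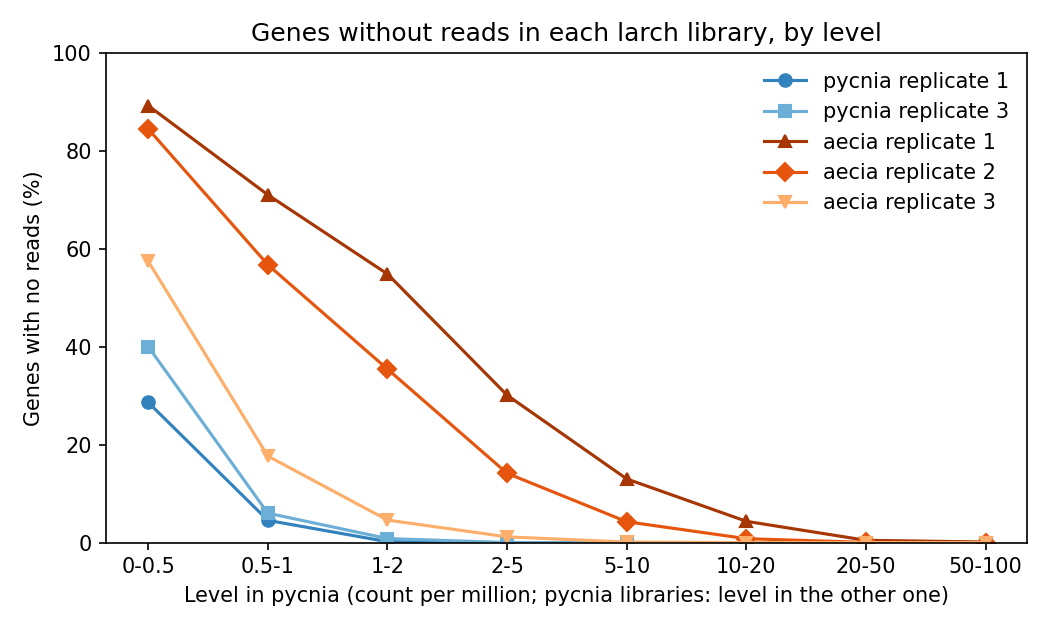
Share of genes without reads (%) in each pycnia and aecia library, by the level of the gene in pycnia (CPM; for a pycnia library, the level in the other pycnia library). At 2 to 5 CPM the share is 30.1% in aecia replicate 1, 14.1% in aecia replicate 2, 1.17% in aecia replicate 3 and 0 in both pycnia libraries.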

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

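Leaving out aecia replicates 1 and 2, counting only genes of at least 20 CPM, library totals alone, quality weights and robust estimation were chosen after seeing the data. Over all alternatives run, the counts against basidia lay at 2289 to 4812 (higher in pycnia), 1790 to 4451 (lower in pycnia), 2350 to 4562 (higher in aecia) and 2192 to 4365 (lower in aecia). They stayed within 1.5 times the reported counts except with library totals alone, which gave 1790 lower in pycnia and 2192 lower in aecia, and moved the median of all genes. The counts for aecia against pycnia (256 higher, 358 lower) were 61 and 122 with only these stages fitted, 43 and 105 at an adjusted p under 0.01 and 110 higher at an absolute log2 fold change of at least 1, settings with fewer libraries or a stricter threshold. They were 720 and 693 with DESeq2, 623 lower with limma-voom, 594 and 624 with quality weights and 1774 and 2053 with aecia replicates 1 and 2 left out; the cause was not tested. With each library left out in turn they ranged from 8 to 858 higher and from 56 to 1153 lower. Filters, size factors, upper-quartile factors, thinning, robust estimation and library totals left both within 1.5 times.

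The replicate block gave 53 higher and 117 lower genes for aecia against pycnia, and moved no count against basidia by over 1.5 times. Under it, edgeR adjusted p was 0.0956 for Mlp37534, 0.0727 for Mlp85159, 0.114 for Mlp60374, 0.152 for Mlp124499 and 0.103 for Mlp107772 in that comparison, and 0.136 for Mlp124256 in aecia against basidia, so these calls were lost. Nothing in the labels says that a shared number marks a shared batch. Deviations of same-numbered libraries from their stage means correlated at -0.06 to 0.03. This cannot exclude a shared batch, because deviations from the mean of so few libraries depend on each other, and those of the pycnia libraries mirror each other. The log2 fold change of Mlp72983 between aecia and pycnia, never called, changed sign to -0.23 under the block, -0.018 without aecia replicate 1 (highest 0.15 over single libraries left out, without aecia replicate 3), -0.091 without aecia replicates 1 and 2, -0.043 with library totals and -0.032 with quality weights. That of Mlp123218 became 0.072 without aecia replicates 1 and 2. The direction of the candidate effector list in that comparison turned under the replicate block (camera adjusted p = 0.997) and without aecia replicate 2 or 3 (0.762 and 0.770), within a range of 0.557 to 0.895 over single libraries left out; the cause was not tested. The list passed in no comparison under any setting run.

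Of the remaining values for candidate effectors over all settings, 386 stayed on their side of the threshold, 32 lost a call and 16 gained one. For other named genes the numbers were 415, 19 and 7, with no change of sign. Counts thinned to the smallest library gave 266 higher and 341 lower genes for aecia against pycnia, and 3352 and 2780 for pycnia against basidia, so unequal depth moved neither by over 1.5 times. Depth limits genes near the 3-read floor most.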

Other observations

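The tests of the falls on genes chosen without aecia replicate 3, with and without a pycnia library left out, and the naming of the genes with reads in basidia alone, were chosen after related results were seen. The predictions for the other tests were written before their results but after the patterns had been noticed, and those for aecia replicate 2 in the last pattern were added after the results for aecia replicate 1. Some genes had at least 10 CPM in 1 stage and no read in another. Of 6742 genes with at least 10 CPM in every pycnia library, 25 (0.371%) had no read in any basidia library, and of 6536 such basidia genes, 13 had no read in pycnia and 22 none in aecia. Of 5967 such aecia genes, 10 had no read in basidia. Of the basidia genes, 5 had no read in either larch stage: Mlp104472 (31.8 CPM), Mlp106321, Mlp112253, Mlp112456 and Mlp124467. Between pycnia and aecia no gene met this rule in either direction. The 25 pycnia genes together held 0.128% ± 0.004 of pycnia reads (SD, n = 2), led by Mlp110449 at 153 CPM.

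Among the 16 listed candidate effectors in the files, 5 had no read in any of the 8 libraries: Mlp124266, Mlp106078, Mlp102036, Mlp124518 and Mlp124305. A further 4 had too few reads to be tested. These were Mlp37347, a candidate located at plasmodesmata, with 2 reads in all, Mlp124357 with 1, Mlp123531 with 16 and Mlp124202 with 31. Only unique reads were counted, so an absence of reads for a gene with a near-identical copy is uncertain.

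Aecia replicates 1 and 2 held no reads for many genes that aecia replicate 3 and pycnia detected, and this share fell with gene level. A candidate explanation is that few RNA molecules entered these 2 libraries, so that which genes were lost was largely random: among 1254 genes at 2 to 10 CPM, 22 lacked reads in both, against 17.0 if the losses were independent (common odds ratio 1.51, 95% interval 0.88 to 2.61). An odds ratio of that width does not exclude some shared loss, and separate changes of expression in each library would also leave the losses independent. A different expression programme in aecia replicate 1 at all levels stays open too: the SD of its log2 ratio to aecia replicate 3 was 1.68 at 10 to 20 CPM and 0.62 above 500 CPM, but this ratio of 0.367 decides nothing, because the SD between the pycnia libraries also fell, from 0.294 to 0.127, a ratio of 0.432. The fall for aecia replicate 1 ended at 50 to 100 CPM, where the SD was 0.63. At higher levels it was 0.56 to 0.62. From 50 to 100 CPM to above 500 CPM, the SD for aecia replicate 2 went from 0.38 to 0.25. That between the pycnia libraries went from 0.17 to 0.13.

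From pycnia to aecia, 162 genes fell and 9 rose by over 4-fold. The imbalance remained with counts thinned to the smallest library, at 161 against 11, a ratio of 14.6. Thinning was a weak test of depth, because every aecia library was deeper than every pycnia library. It also leaves a loss of molecules before sequencing untouched. With aecia replicates 1 and 2 left out, which leaves a single aecia library, the ratio of falls to rises was smaller. Falls still clearly outnumbered rises in that fit. Random loss of reads from aecia replicates 1 and 2 stays open for part of the imbalance. In a fit without aecia replicate 3, 16 genes rose by over 4-fold, 8 of them also in that library, and 618 fell. Of the 618, 464 were lower in aecia replicate 3, 200 by over 4-fold, and 308 were less than 2-fold lower or not lower. Their median log2 ratio to pycnia was -1.02 (95% bootstrap interval -1.27 to -0.85). The bootstrap resampled genes as if independent, so its interval holds no spread between aecia libraries. Pycnia served both to choose and to measure these genes, which pulls that median down. With pycnia replicate 1 or 3 also left out of the choice, fewer genes fell. Their medians were -1.23 or -1.15 to the library left out, against -1.58 to the library used. Over these genes the median log2 ratio of the pycnia library left out to that used was -0.16 in each case. These are smaller sets of genes than the 618, so they do not correct the median of -1.02. A change in the mix of fungal cell types in the needle, and a difference between inoculations, were not tested and stay open.

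Genes abundant on one host all had reads on the other, a trace for some of them. None of the 204 genes of at least 1000 CPM in basidia lacked reads in any larch library. Their lowest levels were 0.0079% to 0.040% of the basidia level. Per larch library, 37 to 51 of the 204 lay under 0.2% of that level, and the rest lay higher. Likewise, none of the 77 genes of at least 1000 CPM in the larch stages lacked reads in any basidia library. Their lowest levels were 0.021%, 0.053% and 0.023% of the larch level in basidia replicates 1, 2 and 3. In these libraries 14, 7 and 14 of the 77 lay under 0.2%. If molecules were lost from aecia replicates 1 and 2, RNA truly present would pass through the same loss of molecules and give 1 to 10 reads no more often for genes abundant in basidia than for others. Among detected genes under 2 CPM in pycnia, 1 to 10 reads were more frequent for genes above 100 CPM in basidia than for genes under 1 CPM. The ratios were 3.76 and 2.49 (Fisher's exact test across genes, p = 6.2e-19 and 1.3e-15). This does not decide about RNA of the other stage in the tissue, which stays open. A loss of molecules was not established, and the compared groups of genes were not matched for their level in aecia. Among genes also under 2 CPM in aecia replicate 3, the ratios were 3.21 and 2.36 (Fisher's exact test across genes, p = 1.8e-15 and 2.8e-14). No prediction was written for this restriction, which limits the level without matching it. Reads assigned to the wrong library are a candidate explanation that stays open: genes with 1 to 10 reads had median basidia levels of 72.6 and 1.62 CPM, 2025 and 56.5 times those of genes with none, but this decides nothing, because the genes with none were nearly silent in basidia as well (0.036 and 0.029 CPM). The other libraries were not tested.

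Of the 10 splits of the 3 basidia and 3 aecia libraries into groups of 3, 1 gave as many called genes as the real split, which is that split itself, with 6705 genes by edgeR. The highest count among the other splits was 0. With 10 splits, a share under 0.05 cannot be reached.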
